A study of Mus musculus with 6 samples.

How the data were processed

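RNA was sequenced from mouse LSK cells and from mouse bone marrow cells transformed with MLL-AF9, on a mixed 129/Sv and C57BL/6 background. Per the labels' protocols, LSK libraries were made from about 50 sorted cells of 2-month-old littermates with PCR amplification, and MLL-AF9 libraries from extracted RNA with a TruSeq kit. The MLL-AF9 cells labelled Mll4 deleted and the intact ones were sorted after infection with a Cre or an empty retrovirus, so Cre goes with deletion. The FOXO3 and empty-vector cells came from a separate transformation. The files as deposited hold raw read counts, whole numbers per NCBI gene number for 23282 genes, 1 file per library. Per the submitters' processing notes, the tools included TopHat2 2.0.11 and Bowtie 0.12.8 and the genome build mm9. The counting tool, the annotation and the use of strand are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies may therefore be shared, and values of such genes are uncertain.

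Gene names were taken from the RefSeq gene table of GRCm38.p6, another build than mm9, so it served for names only and no coordinates are given; 23185 of the 23282 gene numbers matched and 97 did not. The unmatched numbers took 1.01% of the counts of the empty-vector library and 0.0374% to 0.269% of the others, and stayed in the library totals and tests. Total counts ranged from 25895041 to 61950773 per library. The 10 most abundant genes took 19.1% and 20.1% of the counts in the LSK libraries, 6.55% and 7.62% in the pair labelled Mll4 deleted, 13.4% and 17.4% in the intact pair, 4.62% and 4.59% with FOXO3 and 4.91% with the empty vector. CPM values are counts scaled by the library total alone, whereas fold changes use TMM scaling factors, so their ratios differ slightly.

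Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default expression filter and the quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 7 MLL-AF9 libraries entered 1 fit with a coefficient for each of the 4 groups, because 1 group holds a single library. Mll4 loss was the group labelled Mll4 deleted (2 libraries) minus the intact group (2), and FOXO3 expression was the FOXO3 group (2) minus the empty vector (1). Errors after ± are SE for log2 fold changes and SD for CPM. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. With an estimated correlation none of the list calls held in either comparison. The 26 lists covered FOXO targets, antioxidant genes, p53 targets, DNA repair, primary granules, neutrophils, macrophages, MLL-AF9 targets, stem cells, the cell cycle, CDK inhibitors, COMPASS, interferon response, immediate early genes, amino acid stress, glycolysis, oxidative phosphorylation, ribosomal proteins and sex-linked genes. The others marked B cells, T and NK cells, lymphoid priming, erythroid cells, megakaryocytes, mast cells with basophils and eosinophils, and stroma. B cell and CDK inhibitor lists had too few expressed members to be placed in LSK cells.

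The LSK libraries, 1 per genotype, were compared by log2 ratios of CPM with 95% exact binomial (Clopper-Pearson) intervals, with no test. The median of each list was placed among 10000 random lists of the same size matched on mean expression, over members with a mean of at least 1 CPM. The limit for a count of 0 is 3 counts.

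The groups, tests, lists and alternatives were fixed before the data were examined, except the alternatives that sum the FOXO3 pair or add the sex of the library, which were chosen after seeing the data. The rule for named genes, also fixed before, took Kmt2 genes and Foxo3, a fixed set of 9 genes, the 10 highest and 10 lowest fold changes among called genes with a mean of at least 10 CPM and no overlap between groups, and the 4 members of each list with the smallest p. In LSK cells it took 2 members per list and genes of at least 50 CPM. Where 5 or fewer members of a list passed, they are named without values even if that rule does not take them, having been chosen after their values were seen. Some genes that fit these rules are not reported here. Alternatives were RLE, upper quartile and total-count scaling, no filter or a mean of at least 5 CPM, robust estimation, DESeq2 1.42.0, only the libraries compared, the replicate number as a block, a 2-fold threshold and each library left out in turn. The test was tried on simulated data with 200 of 14990 genes changed by known folds. The FOXO3 pair was drawn from 1 culture in 3 runs and from separate cultures in another 3. With the FOXO3 pair drawn from 1 culture, 59.3% of 4-fold and 13.3% of 2-fold changes were recovered for Mll4 loss, and 44.3% and 7.33% for FOXO3. A run of this 1-culture setting gave a mean of 12.3 false beside 72.7 true calls for Mll4 loss and 24.7 beside 51.7 for FOXO3. In the same runs with the pair summed the means were 17.3 beside 73.0 and 9.67 beside 24.3. In each of these cases false calls made up a larger share than the threshold of 0.05 aims at. Over the runs of both settings, camera found the 1 list changed for Mll4 loss in 6 of 6, with 2 calls among unchanged lists. No list was changed for FOXO3, where camera made 1 call, so the recovery of lists was not tried there. Simulated genes varied independently of each other, whereas the cell cycle list had an estimated correlation of 0.525 in the data. These runs therefore do not test list calls at the preset correlation among genes that vary together. Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9 served for the LSK intervals and the plots.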

Results

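RNA of mouse blood-forming cells was sequenced, and read counts per gene were given for 9 libraries from 6 samples. LSK cells are bone marrow cells that lack lineage markers and carry Sca1 and c-Kit, a fraction that holds stem cells and early progenitors. MLL-AF9 is a leukaemia fusion oncogene that lets bone marrow cells grow in culture after retroviral transfer. Mll4, also named Kmt2d, encodes a histone H3 lysine 4 methyltransferase, and FOXO3 is a transcription factor tied to stress resistance. The groups were LSK cells labelled Mll4 deleted (1 library) and wild type (1), and MLL-AF9 cells labelled Mll4 deleted through a Cre retrovirus (2) or carrying intact Mll4 and an empty vector (2). From a separate transformation of marrow labelled Mll4-null came MLL-AF9 cells with a FOXO3 retrovirus (2) or an empty vector (1). Totals were 25895041 counts in the LSK library labelled Mll4 deleted and 26599883 in the wild type one. In MLL-AF9 cells they were 61950773 and 31713351 in the pair labelled Mll4 deleted, and 48102130 and 49491900 in the intact pair. The FOXO3 libraries held 37083939 and 44883561 counts and the empty-vector library 52518578. Intervals and limits cover counting error only, since reads copied by PCR are not independent molecules.

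The 2 libraries of a sample were compared before they were averaged. The chi-square of their counts per degree of freedom was 201 in the pair labelled Mll4 deleted, 154 in the intact pair and 2.02 in the FOXO3 pair. The FOXO3 pair thus lay above sampling noise, with 11.8% of its genes at an unadjusted p under 0.05, and entered as 2 libraries. Because it was so much closer than the other pairs, counts of calls with the pair summed into 1 library are given beside the main ones. Nothing in the labels says that the libraries of a sample came from separate cultures, so the p-values measure only the spread between these libraries, which in the FOXO3 pair may be technical. Xist, the RNA of the inactive X chromosome, stood at 771 and 2.21 CPM in the pair labelled Mll4 deleted and at 1.08 and 687 CPM in the intact pair. The Y-linked Ddx3y stood at 0.161, 41.3, 52.0 and 0.121 CPM in the same order, so each of these pairs held 1 library of either sex. The libraries within each of these pairs therefore came from cells of different mice, which the labels do not state. For the FOXO3 pair this stays open. The FOXO3 and empty-vector libraries carried Ddx3y at 99.3, 98.5 and 92.2 CPM.

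Kmt2d (NCBI gene 381022), the targeted gene, was counted at 84.7 ± 15.5 CPM in the libraries labelled Mll4 deleted and at 70.6 ± 12.6 CPM in the intact libraries (SD, n = 2 each). Its log2 fold change was −0.01 ± 0.16 (SE), with an adjusted p of 0.972 by edgeR's quasi-likelihood test. It stood at 109 ± 8.85 CPM with FOXO3 (n = 2) and 116 CPM with the empty vector, both in cells labelled Mll4-null. In LSK cells Kmt2d was higher in the library labelled Mll4 deleted, with 359 counts (13.9 CPM) against 50 counts (1.88 CPM) in the library labelled wild type. That log2 ratio of 2.88 (95% exact binomial interval 2.45 to 3.34) goes against the label. Counts were summed over the whole gene, and the exons that the floxed allele loses are not given in the sources used here, so these values do not check the deletion. The libraries are therefore called by their labels, and each direction given for Mll4 loss rests on those labels. Among the related methyltransferase genes, Kmt2a, Kmt2b, Kmt2c and Kmt2e had adjusted p values of 0.131, 0.835, 0.11 and 0.0908 for Mll4 loss.

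Mll4 loss in MLL-AF9 cells was examined to see which genes differ in transformed cells labelled Mll4 deleted. In the libraries labelled Mll4 deleted, the lists of cell cycle and primary granule genes were higher, and those of macrophage, platelet and immediate early genes lower. In a test of each list against all other genes (camera) they had adjusted p = 1.08e-18 to 0.0009, and adjusted p = 0.308 to 0.43 with an estimated correlation. Prtn3 (19152), a serine protease of the first neutrophil granules, rose from 159.7 ± 38.2 to 1873 ± 567 CPM, and the replication-linked chromatin gene Uhrf1 (18140) from 34.3 ± 0.560 to 139.6 ± 8.50 CPM (SD, n = 2 each). Itgax (16411), the CD11c integrin of macrophages and dendritic cells, fell from 431 ± 95.6 to 59.6 ± 22.8 CPM. The chemokine gene Ccl4 (20303) fell from 185 ± 43.4 to 29.5 ± 1.51 CPM. Of 14997 genes tested, 2237 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1196 higher and 1041 lower. Of these, 461 and 549 differed at least 2-fold. With libraries scaled by their total counts, 2940 were higher and 600 lower, as the median log2 fold change of all genes moved from −0.03 to 0.24, so changes are relative to the main scaling. The count was 312 with the FOXO3 pair summed (184 higher and 128 lower, all among the 2237), 302 and 314 without FOXO3 library 1 or 2, and 787 and 1199 without intact library 1 or 2. In a fit of the 4 compared libraries alone edgeR called 0 genes (smallest adjusted p = 0.0514, with 3498 genes at an unadjusted p under 0.05), and DESeq2 called 3695 in the 7 libraries. In simulated data whose FOXO3 pair came from 1 culture, 10.6% of unchanged genes reached an unadjusted p under 0.05 in the fit of 7 libraries, against 4.79% with the pair summed. Among the calls of both fits, false ones still made up a larger share than the threshold aims at.

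**Figure D1:**
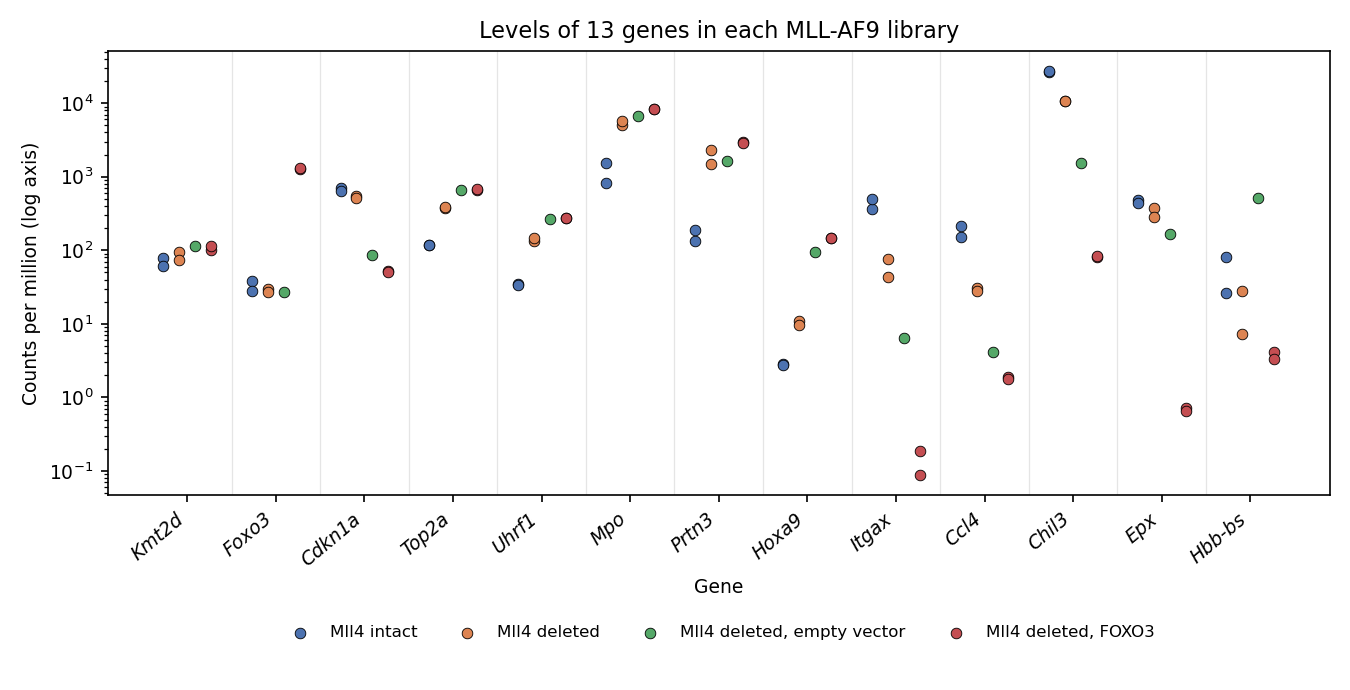
CPM (log axis) of 13 genes in each of the 7 MLL-AF9 libraries, coloured by group, with 1 point per library. Itgax and Ccl4 lie lower, and Prtn3, Top2a and Uhrf1 higher, in both libraries labelled Mll4 deleted than in both intact libraries, and Foxo3 stands at 1292 and 1309 CPM in the FOXO3 libraries against 27.3 with the empty vector.

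Cell cycle genes moved together. Of the 39 tested, 32 rose and the other 7 did not pass, and all 39 rose when adjusted over the list alone, with a median log2 fold change of 1.20. With the FOXO3 pair summed 16 passed. Camera placed the list higher (adjusted p = 1.08e-18, and adjusted p = 0.308 with an estimated correlation). Top2a, the topoisomerase of dividing cells (log2 fold change 1.39 ± 0.11, adjusted p = 0.00739), the helicase subunit Mcm3 (1.57 ± 0.14, adjusted p = 0.0079) and the ribonucleotide reductase subunit Rrm2 (1.66 ± 0.15, adjusted p = 0.00791) were among them. DNA repair genes had 20 of 41 members higher and 1, Lig4, lower, or 24 and 2 when adjusted over the list alone and 6 and 0 with the pair summed. For DNA repair camera was higher (adjusted p = 4.61e-07, and adjusted p = 0.308 with an estimated correlation). The replicative ligase Lig1 (1.68 ± 0.16) rose.

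Genes of the primary granules, which form at the promyelocyte stage, had 7 of 13 members higher, 11 when adjusted over the list alone and 4 with the pair summed, with a median of 1.05. For primary granules camera was higher (adjusted p = 2.23e-06, and adjusted p = 0.308 with an estimated correlation). Besides Prtn3 (log2 fold change 3.26 ± 0.32, adjusted p = 0.00829), the membrane protein gene Ms4a3 (2.69 ± 0.14, adjusted p = 0.0073) and cathepsin G, Ctsg (1.77 ± 0.18, adjusted p = 0.00925), rose. Elane, neutrophil elastase (2.87 ± 0.38, adjusted p = 0.0133), missed the threshold without intact library 1 (adjusted p = 0.0642). Mpo, myeloperoxidase, stood at 5427 ± 427 against 1178 ± 503 CPM (log2 fold change 1.90 ± 0.35, adjusted p = 0.0252). It missed the threshold with the FOXO3 pair summed (adjusted p = 0.0698) and without the library labelled Mll4 deleted 2 (adjusted p = 0.0503).

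MLL-AF9 target genes had 6 higher and 2, Eya1 and Zeb2, lower of 29, or 11 and 3 when adjusted over the list alone and 3 and 0 with the pair summed. For these targets camera was higher (adjusted p = 0.0102, and adjusted p = 0.345 with an estimated correlation), and missed the threshold without the library labelled Mll4 deleted 1 (adjusted p = 0.199). Hoxa9, a homeobox gene that MLL fusions keep active, rose from 2.84 ± 0.0717 to 10.3 ± 1.02 CPM (log2 fold change 1.58 ± 0.12, adjusted p = 0.0073), and the progenitor transcription factor Myb rose (1.74 ± 0.21). Myc (0.65 ± 0.17, adjusted p = 0.0586) and Meis1 (0.24 ± 0.60, adjusted p = 0.81) did not pass. Without the library labelled Mll4 deleted 1, Meis1 stood at −1.11 (adjusted p = 0.0245).

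With the FOXO3 pair summed, no gene of the glycolysis, oxidative phosphorylation and ribosomal lists kept its call. Glycolysis genes had 5 of 19 members higher (Pfkl, Pfkm, Tpi1, Pgk1 and Pkm), 6 when adjusted over the list alone, with a median of 0.44. For glycolysis camera gave adjusted p = 0.00465, and adjusted p = 0.308 with an estimated correlation. Tpi1, triose phosphate isomerase (0.75 ± 0.12), missed the threshold with the FOXO3 pair summed (adjusted p = 0.0795) and without intact library 1 (adjusted p = 0.0565). Oxidative phosphorylation genes had Ndufa4 and Sdha higher of 41, 1 when adjusted over the list alone, with a median of 0.29 and 39 positive estimates. For oxidative phosphorylation camera gave adjusted p = 2.71e-05, and adjusted p = 0.538 with an estimated correlation. Ribosomal protein genes, many with near-identical pseudogenes, had Rps2, Rpl3 and Rps21 higher of 71, with a median of 0.14. Adjusted over the list alone 0 passed by edgeR, with 15 at an unadjusted p under 0.05 and 14 called by DESeq2. For ribosomal proteins camera gave adjusted p = 0.000254, and adjusted p = 0.614 with an estimated correlation, and missed the threshold without intact library 2 (adjusted p = 0.118).

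Monocyte and macrophage genes had 11 of 39 members lower, or 18 lower and 4 higher when adjusted over the list alone and 4 lower with the pair summed, with a median of −0.92. For macrophages camera was lower (adjusted p = 0.0009, and adjusted p = 0.43 with an estimated correlation). Itgax (log2 fold change −3.15 ± 0.36, adjusted p = 0.0109), Ccl4 (−2.94 ± 0.23, adjusted p = 0.0073) and the beta-glucan receptor Clec7a (−2.01 ± 0.24, adjusted p = 0.0112) fell. Csf1r, the receptor for the macrophage growth factor CSF1 (log2 fold change −0.42 ± 0.45, adjusted p = 0.558), and the integrin Itgam (−1.05 ± 0.29, adjusted p = 0.0647) did not pass. Neutrophil genes had 8 lower and 1, the antimicrobial peptide gene Camp, higher of 36, or 13 and 1 when adjusted over the list alone and 3 and 1 with the pair summed. For neutrophils camera was lower (adjusted p = 0.00431, and adjusted p = 0.43 with an estimated correlation), and missed the threshold without intact library 1 (adjusted p = 0.142). Chil3, whose reads may be shared with close chitinase-like copies, fell from 27040.0 ± 496 to 10720.0 ± 166 CPM, the gelatinase Mmp9 fell (−1.97 ± 0.23), and Camp rose (1.80 ± 0.16). Interferon response genes had Ifit1, Irf9, Rsad2, Usp18 and Parp14 lower and Cxcl10 higher of 40, or 9 and 1 when adjusted over the list alone and 1 and 0 with the pair summed. For interferon genes camera was lower (adjusted p = 0.00213, and adjusted p = 0.43 with an estimated correlation), and missed the threshold without the library labelled Mll4 deleted 1 (adjusted p = 0.106).

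Megakaryocyte and platelet genes had 10 of 16 members lower, also 10 when adjusted over the list alone but 2 with the FOXO3 pair summed, with a median of −2.03. For platelet genes camera was lower (adjusted p = 7.35e-06, and adjusted p = 0.308 with an estimated correlation). The clotting factor Vwf fell from 173 ± 8.27 to 59.3 ± 2.23 CPM (log2 fold change −1.83 ± 0.13, adjusted p = 0.0073) and the platelet receptor Treml1 from 14.7 ± 3.28 to 2.28 ± 0.526 CPM (−2.99 ± 0.37, adjusted p = 0.0118). Erythroid genes had 5 of 18 lower (among them Car1, Ermap, Sptb and Ank1), or 7 lower and 1 higher when adjusted over the list alone and 1 lower with the pair summed. Their median was −1.39, or −1.26 with 2 members at 0 in a group set to their bound. For erythroid genes camera was lower (adjusted p = 0.00627, and adjusted p = 0.43 with an estimated correlation), and missed the threshold without the library labelled Mll4 deleted 2 (adjusted p = 0.0878). The red cell skeleton gene Ank1 fell from 1.34 ± 0.346 to 0.119 ± 0.0544 CPM (−3.82 ± 0.43). Stromal and endothelial genes had Col1a1 and Acta2 lower of 11, also 2 when adjusted over the list alone and 0 with the pair summed (adjusted p = 0.0195, and adjusted p = 0.308 with an estimated correlation).

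Immediate early genes had 9 of 24 members lower, or 12 lower and 1 higher when adjusted over the list alone and 3 lower with the FOXO3 pair summed. For immediate early genes camera was lower (adjusted p = 0.000159, and adjusted p = 0.308 with an estimated correlation), and the phosphatase Dusp1 (log2 fold change −1.28 ± 0.11, adjusted p = 0.00766) and the AP-1 subunit Jund (−1.04 ± 0.097, adjusted p = 0.00791) fell. Genes induced by p53 had 10 lower and 1, Ckap2, higher of 30, or 11 and 1 when adjusted over the list alone and 1 and 0 with the pair summed. For p53 targets camera was lower (adjusted p = 0.00465, and adjusted p = 0.308 with an estimated correlation). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, fell from 666 ± 41.0 to 526 ± 26.9 CPM (log2 fold change −0.62 ± 0.11, adjusted p = 0.0212), a call not kept with the FOXO3 pair summed (adjusted p = 0.135). Genes described as FOXO targets had 10 lower and 2, Sesn1 and Ddb1, higher of 37, or 14 and 3 when adjusted over the list alone and 3 and 0 with the pair summed. For FOXO targets camera was lower (adjusted p = 0.0114, and adjusted p = 0.308 with an estimated correlation). They included the interleukin 7 receptor Il7r (−2.36 ± 0.18), the growth arrest gene Gadd45a (−2.26 ± 0.21) and cyclin D1, Ccnd1 (−1.79 ± 0.19), a cell cycle activator that FOXO factors are known to repress. Foxo3 itself did not pass (log2 fold change −0.47 ± 0.13, adjusted p = 0.0688).

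Antioxidant genes had 4 higher (Sod1, Gsr, Nqo1 and Sesn1) and 5 lower (Hmox1, Msra, Msrb1, Sesn2 and Nfe2l2) of 44, or 6 and 5 when adjusted over the list alone and 1 and 0 with the FOXO3 pair summed, and the list did not pass (adjusted p = 0.913). Their median of 0.02 and camera were positive and their mean negative. Glutathione reductase, Gsr, rose (log2 fold change 1.28 ± 0.14, adjusted p = 0.00986), whereas the mitochondrial superoxide dismutase Sod2 (−0.18 ± 0.20, adjusted p = 0.577) and catalase, Cat (−0.21 ± 0.13, adjusted p = 0.289), did not pass. Amino acid stress genes had 7 lower and 2, Psat1 and Phgdh, higher of 22, or 8 and 3 when adjusted over the list alone and 3 and 0 with the pair summed (adjusted p = 0.0541, and adjusted p = 0.0471 with the pair summed). With an estimated correlation the list had adjusted p = 0.454 and adjusted p = 0.511. Among its members Ddit3, the stress factor CHOP (−2.71 ± 0.21), Trib3 (−3.58 ± 0.32) and Atf5 (−2.25 ± 0.14) fell. COMPASS genes, the lysine 4 methyltransferases and their partners, had Dpy30, Paxip1, Men1 and Hcfc1 higher and Ncoa6 lower of 18, or 7 and 2 when adjusted over the list alone (adjusted p = 0.102). None of these 5 COMPASS calls was kept with the pair summed. Stem cell and progenitor genes had 6 lower and 1, Etv6, higher of 37, or 7 and 7 when adjusted over the list alone and 2 and 0 with the pair summed (adjusted p = 0.134). The transglutaminase Tgm2 of that list fell (−2.28 ± 0.12), and the median of −0.16 turned positive with total-count scaling.

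The CDK inhibitors Cdkn1a and Cdkn1c were lower of 7, the B cell genes Blnk, Cd22 and Bank1 of 8, and Il7r of 6 lymphoid priming genes. Adjusted over the list alone the counts were 2, 3 and 3, with the FOXO3 pair summed 0, 0 and 1, and the lists did not pass (adjusted p = 0.125, 0.149 and 0.0544). Summing moved the last to an adjusted p of 0.0369, and adjusted p = 0.389 with an estimated correlation. T and NK cell genes had Lck and Cd28 lower and Tcf7 higher of 18, the same counts when adjusted over the list alone and 1 and 0 with the pair summed (adjusted p = 0.902). Their median of −0.17 and camera were negative and their mean positive, and the median turned positive with total-count scaling. Mast cell, basophil and eosinophil genes had only Epx lower of 24, a call that ended with the pair summed and without intact library 1 or 2 (adjusted p = 0.103 and 0.106). Adjusted over the list alone 0 passed by edgeR, with 6 at an unadjusted p under 0.05 and 6 called by DESeq2 (list adjusted p = 0.922). Their median of 0.30 and mean were positive and camera negative, and without the library labelled Mll4 deleted 1 the median was −0.82 (adjusted p = 0.0331). The mean log2(CPM + 1) of that list was 6.78 and 5.04 in the pair labelled Mll4 deleted and 6.36 and 5.53 in the intact pair.

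The largest rises by fold included Penk, the proenkephalin gene (log2 fold change 5.00 ± 0.38, adjusted p = 0.0073), the ceramide synthase Cers4 (2.99 ± 0.22, adjusted p = 0.0073) and the myeloid gene Plac8 (2.53 ± 0.22, adjusted p = 0.00766). Among the largest falls were Klk1b11 of the closely related kallikrein cluster, where reads may be shared (log2 fold change −4.75 ± 0.23, adjusted p = 0.0073), the growth factor Hbegf (−3.77 ± 0.46, adjusted p = 0.0112) and the zinc transporter Slc39a2 (−3.74 ± 0.27, adjusted p = 0.0073). The integrin Itgad (−3.57 ± 0.38), the arginase Arg2 (−3.46 ± 0.21) and the gap junction gene Gja5 (−3.29 ± 0.33) fell as well. Tpsg1, a tryptase with close copies (6.94 ± 1.41), had an adjusted p of 0.0771 with the FOXO3 pair summed and of 0.128 and 0.144 without intact library 1 or 2. The chemokine Ccl24 (3.14 ± 0.68) had 0.0825 and then 0.0931 and 0.14 in the same order, and Retnlg (−3.59 ± 0.68) had 0.0753, 0.0975 and 0.0546.

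FOXO3 expression in MLL-AF9 cells labelled Mll4-null was examined against the empty vector to see what FOXO3 does to their transcriptome. Foxo3 (56484) stood at 1300.0 ± 11.5 CPM in the FOXO3 libraries (SD, n = 2) against 27.3 CPM with the empty vector (log2 fold change 5.53 ± 0.22, adjusted p = 0.000745), and the counts do not separate the vector's transcript from the cell's own. The erythroid, mast cell, macrophage and neutrophil lists were lower with FOXO3 by camera (adjusted p = 4.98e-12 to 0.00035, and adjusted p = 0.612 to 0.712 with an estimated correlation). Epx, eosinophil peroxidase (13861), fell from 167 to 0.687 ± 0.0580 CPM, and the macrophage elastase Mmp12 (17381) from 111 to 0.939 ± 0.351 CPM. The carbonic anhydrase Car2 (12349) of red cells fell from 109.5 to 2.98 ± 0.0908 CPM, while Gpx3, a glutathione peroxidase (14778), rose from 22.2 to 189.7 ± 1.44 CPM. Of 14997 genes tested, 1069 passed an adjusted p of 0.05, 330 higher and 739 lower, and 250 and 678 of these differed at least 2-fold. With the FOXO3 pair summed, 178 passed (32 higher and 146 lower, all among the 1069), and fewer still without FOXO3 library 1 or 2. Libraries of the other comparison enter through the shared spread. Leaving out a library labelled Mll4 deleted raised the count, and leaving out an intact library lowered it. With the FOXO3 pair summed, or 1 of its libraries left out, the comparison is 1 library against 1. All of its spread then comes from the pairs labelled Mll4 deleted and intact. Its p-values then measure no variation between FOXO3 or between empty-vector cultures. The empty-vector library has no replicate and is assumed to vary like the other groups, and in simulated data whose FOXO3 pair came from 1 culture, 15.3% of unchanged genes reached an unadjusted p under 0.05 in this fit, against 4.86% with the pair summed. Here too, false calls made up a larger share than the threshold aims at, also with the pair summed.

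Erythroid genes had 14 of 18 members lower, 16 when adjusted over the list alone but 3 with the FOXO3 pair summed, with a median log2 fold change of −4.68. With FOXO3 camera placed erythroid genes lower (adjusted p = 4.98e-12, and adjusted p = 0.612 with an estimated correlation). Car2 (log2 fold change −5.25 ± 0.36, adjusted p = 0.00247) and Ank1 (−6.88 ± 0.48, adjusted p = 0.00247) fell, as did the red cell transcription factor Klf1 (−4.27 ± 0.42, adjusted p = 0.00641) and the globin gene Hbb-bs, which has a near-identical copy (−7.14 ± 0.94, adjusted p = 0.0142). The mean log2(CPM + 1) of the erythroid list was 3.44 in the empty-vector library, 1.16 and 1.13 in the FOXO3 libraries and 1.34 to 1.90 in the other 4 MLL-AF9 libraries. Mast cell, basophil and eosinophil genes had 8 of 24 lower, 9 when adjusted over the list alone but 1 with the pair summed, with a median of −2.65. With FOXO3 camera placed mast cell genes lower (adjusted p = 0.00035, and adjusted p = 0.712 with an estimated correlation). Epx (log2 fold change −7.97 ± 0.24, adjusted p = 0.000745) and Prg2, the eosinophil major basic protein (−6.70 ± 0.71, adjusted p = 0.00712), were among the members that fell. For Klf1, Hbb-bs and Prg2 the adjusted p was 0.059, 0.0928 and 0.0576 with the FOXO3 pair summed, and 0.0592 to 0.106 without FOXO3 library 1 or 2.

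Monocyte and macrophage genes had 16 of 39 members lower and 1, Tlr4, higher, or 28 and 1 when adjusted over the list alone but 3 and 0 with the FOXO3 pair summed. Their median was −1.90, or −1.84 with 4 members at 0 in a group set to their bound. Camera placed macrophage genes lower with FOXO3 (adjusted p = 4.71e-10, and adjusted p = 0.612 with an estimated correlation). The mannose receptor Mrc1 fell from 43.3 to 1.98 ± 0.130 CPM (log2 fold change −4.49 ± 0.35, adjusted p = 0.00365). Osteopontin, Spp1 (−4.71 ± 0.46, adjusted p = 0.00623), and the lysosomal protease Ctss (−5.12 ± 0.52, adjusted p = 0.00657) fell too, with adjusted p values of 0.0551 and 0.0554 once the pair was summed and of 0.0579 to 0.0615 without FOXO3 library 1 or 2. Neutrophil genes had 10 of 36 lower, or 17 lower and 2 higher when adjusted over the list alone and 3 lower with the pair summed. With FOXO3 camera placed neutrophil genes lower (adjusted p = 0.00035, and adjusted p = 0.624 with an estimated correlation), with Chil3 at 82.2 ± 0.325 against 1521 CPM (log2 fold change −4.26 ± 0.17, adjusted p = 0.000745), the annexin Anxa1 (−4.98 ± 0.32) and the surface protease Adam8 (−3.69 ± 0.21) among them.

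Stem cell and progenitor genes had 6 lower and 1, Tgm2, higher of 37, or 12 and 2 when adjusted over the list alone and 2 and 1 with the FOXO3 pair summed. Their median was −0.73, or −0.64 with 4 members at their bound. Camera placed stem cell genes lower with FOXO3 (adjusted p = 0.0268, and adjusted p = 0.714 with an estimated correlation). The adhesion receptor Cd48 fell (log2 fold change −4.67 ± 0.36, adjusted p = 0.00335) and Tgm2 rose (2.06 ± 0.16, adjusted p = 0.00343). Immediate early genes had Egr1, Atf3, Ier3 and Hsph1 lower of 24, 13 when adjusted over the list alone and 0 with the pair summed. With FOXO3 camera placed immediate early genes lower (adjusted p = 0.000228, and adjusted p = 0.612 with an estimated correlation). Egr1 (−3.60 ± 0.62) had an adjusted p of 0.143 with the pair summed, and of 0.144 to 0.17 without FOXO3 library 1 or 2.

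Amino acid stress genes were the list placed higher, with Atf5 and Sesn2 higher of 22, 4 when adjusted over the list alone and 0 with the pair summed, 19 positive estimates and a median of 0.61. Camera placed the amino acid stress list higher with FOXO3 (adjusted p = 4.56e-05, and adjusted p = 0.612 with an estimated correlation). Atf5 (log2 fold change 1.18 ± 0.17, adjusted p = 0.0176) and the stress sensor Sesn2 (0.96 ± 0.18, adjusted p = 0.0351) had adjusted p values of 0.104 and 0.182 with the pair summed, and of 0.112 to 0.209 without FOXO3 library 1 or 2. Of 37 genes described as FOXO targets, 2 fell, also 2 when adjusted over the list alone and 1 with the pair summed, and the list did not pass (median −0.01, adjusted p = 0.717), its median turning positive with RLE or total-count scaling. The 2 were Il7r (log2 fold change −4.88 ± 0.28, adjusted p = 0.00191) and Cdkn1a (−0.80 ± 0.13, adjusted p = 0.0229), the latter at 50.7 ± 1.11 against 85.3 CPM. The adjusted p of Cdkn1a was 0.262 with the pair summed and 0.245 to 0.281 without FOXO3 library 1 or 2. Antioxidant genes had Gpx3, Gsr and Sesn2 higher and Nqo1, Hmox1 and Glrx5 lower of 44, or 3 and 6 when adjusted over the list alone and 1 and 0 with the pair summed (adjusted p = 0.717). Gpx3 (log2 fold change 3.05 ± 0.32, adjusted p = 0.00718) and Gsr (1.46 ± 0.18, adjusted p = 0.0106) rose, the latter with an adjusted p of 0.0845 once the pair was summed and of 0.0918 to 0.0951 without FOXO3 library 1 or 2. Sod2 (−0.42 ± 0.24) and Cat (0.16 ± 0.16) did not pass.

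Cell cycle and DNA repair genes showed no call by edgeR with FOXO3. By edgeR 0 of 39 cell cycle genes passed, also adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 1 called by DESeq2 (list adjusted p = 0.717). For DNA repair edgeR called 0 of 41, also adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 3 by DESeq2 (list adjusted p = 0.717). For primary granule genes edgeR called 0 of 13, also adjusted over the list alone, with 6 and 4 (list adjusted p = 0.635). The cell cycle and DNA repair medians, −0.04 and −0.03, turned positive with total-count scaling. MLL-AF9 target genes had Pbx3, Cdk6, Jmjd1c and Runx2 higher and Mef2c, Flt3, Eya1, Sox4 and Adgrg1 lower of 29, or 10 and 7 when adjusted over the list alone and 0 and 1 with the FOXO3 pair summed (adjusted p = 0.115). Their median was 0.35 and camera positive, with a negative mean. Hoxa9 (log2 fold change 0.60 ± 0.14, adjusted p = 0.0654), Meis1 (0.35 ± 0.72, adjusted p = 0.84) and Mpo (0.24 ± 0.41, adjusted p = 0.795) did not pass. Genes induced by p53 had Cdkn1a, Phlda3, Perp, Gdf15 and Sulf2 lower and Sesn2 higher of 30, or 9 and 4 when adjusted over the list alone and 2 and 0 with the pair summed (adjusted p = 0.115). Of 7 CDK inhibitors Cdkn2c, which encodes p18, was higher and Cdkn1a lower, or 1 and 3 when adjusted over the list alone and 0 and 0 with the pair summed (adjusted p = 0.964), with a positive median and a negative mean. Cdkn2c stood at 123 ± 0.960 against 6.00 CPM (log2 fold change 4.31 ± 0.57, adjusted p = 0.0143), with an adjusted p of 0.0657 once the pair was summed and of 0.0695 to 0.0711 without FOXO3 library 1 or 2.

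Other lists did not pass with FOXO3. Interferon response genes had Usp18, Zbp1, Gbp2, Ifi47 and Ly6e lower and Oas1a and Oas1g higher of 40, or 9 and 3 when adjusted over the list alone and 2 and 0 with the FOXO3 pair summed (adjusted p = 0.115). The interferon-induced GTPase Ifi47 fell (log2 fold change −3.08 ± 0.17, adjusted p = 0.00187). COMPASS genes had Rbbp5 higher of 18, glycolysis genes Pfkl lower of 19 and megakaryocyte genes Plek lower of 16, or 1, 0 and 1 when adjusted over the list alone by edgeR, with 3, 4 and 5 at an unadjusted p under 0.05 and 1, 1 and 3 by DESeq2. Their adjusted p values were 0.376, 0.717 and 0.282. B cell genes had Cd79b and Bank1 lower of 8, and T and NK cell genes Cd28 and Tcf7 lower of 18, or 2 and 3 when adjusted over the list alone (adjusted p = 0.115 and 0.115). Lymphoid priming genes had Il7r and Satb1 lower of 6, or 2 lower and 1 higher when adjusted over the list alone (adjusted p = 0.376). Stromal genes had Pecam1 and Pdgfrb lower of 11, or 3 lower and 1 higher when adjusted over the list alone (adjusted p = 0.717). Of the calls in the COMPASS, glycolysis, megakaryocyte, B cell, T and NK cell, lymphoid priming and stromal lists, 1, that of Il7r, was kept with the pair summed. Of 41 oxidative phosphorylation and 71 ribosomal protein genes, edgeR called 0, also adjusted over the list alone, with 6 and 2 at an unadjusted p under 0.05 and 1 and 0 by DESeq2. Their adjusted p values were 0.115 and 0.0729. Of 5 sex-linked genes edgeR called 0 in both comparisons, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 (list adjusted p = 0.948 and 0.802).

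The largest rises with FOXO3 included the X-linked lymphocyte-regulated gene Xlr (log2 fold change 9.01 ± 0.58, adjusted p = 0.00203), which has close copies, the galactosyltransferase B3galt1 (8.61 ± 0.82, adjusted p = 0.00604), cortactin, Cttn (5.43 ± 0.62, adjusted p = 0.00919), and Smpdl3a (5.35 ± 0.56, adjusted p = 0.00712). The junction gene Cgnl1 rose from 0.495 to 65.9 ± 0.155 CPM (adjusted p = 0.000745). Cttn and Smpdl3a each stood at 0.476 CPM with the empty vector, against 21.28 and 20.15 CPM with FOXO3. In the 4 libraries of the other transformation Cttn stood at 14.37 to 54.96 CPM and Smpdl3a at 25.42 to 93.25 CPM. Xlr and B3galt1, by contrast, stood there at 1.515 to 3.567 and 0.042 to 0.274 CPM. With 1 empty-vector library, a low level in it cannot be told apart from a rise with FOXO3, nor a high level in it from a fall. Among the largest falls were the fatty acid receptor Cd36 (log2 fold change −7.60 ± 0.48, adjusted p = 0.00203) and Mmp12 (−6.94 ± 0.52, adjusted p = 0.00312). In the 4 libraries of the other transformation Cd36 stood at 139 to 446.7 CPM, above its 30.29 CPM with the empty vector. Mmp12 stood there at 1224 to 8757 CPM, above its 111 CPM. For Fgf3, by contrast, the empty-vector library at 33.65 CPM lay above those 4, at 0.536 to 1.55 CPM. The growth factor Fgf3 fell (log2 fold change −6.82 ± 0.59, adjusted p = 0.00486) but missed the threshold without FOXO3 library 1 or 2 (adjusted p = 0.0507 and 0.0526). Slc4a5 and Pmp22 among the rises (7.15 ± 1.08 and 4.86 ± 0.72) and Cpne7 and Hmgn3 among the falls (−8.34 ± 1.15 and −7.49 ± 0.97) had adjusted p values of 0.0942, 0.0717, 0.0922 and 0.082 once the pair was summed, and of 0.0752 to 0.112 without FOXO3 library 1 or 2.

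**Figure D2:**
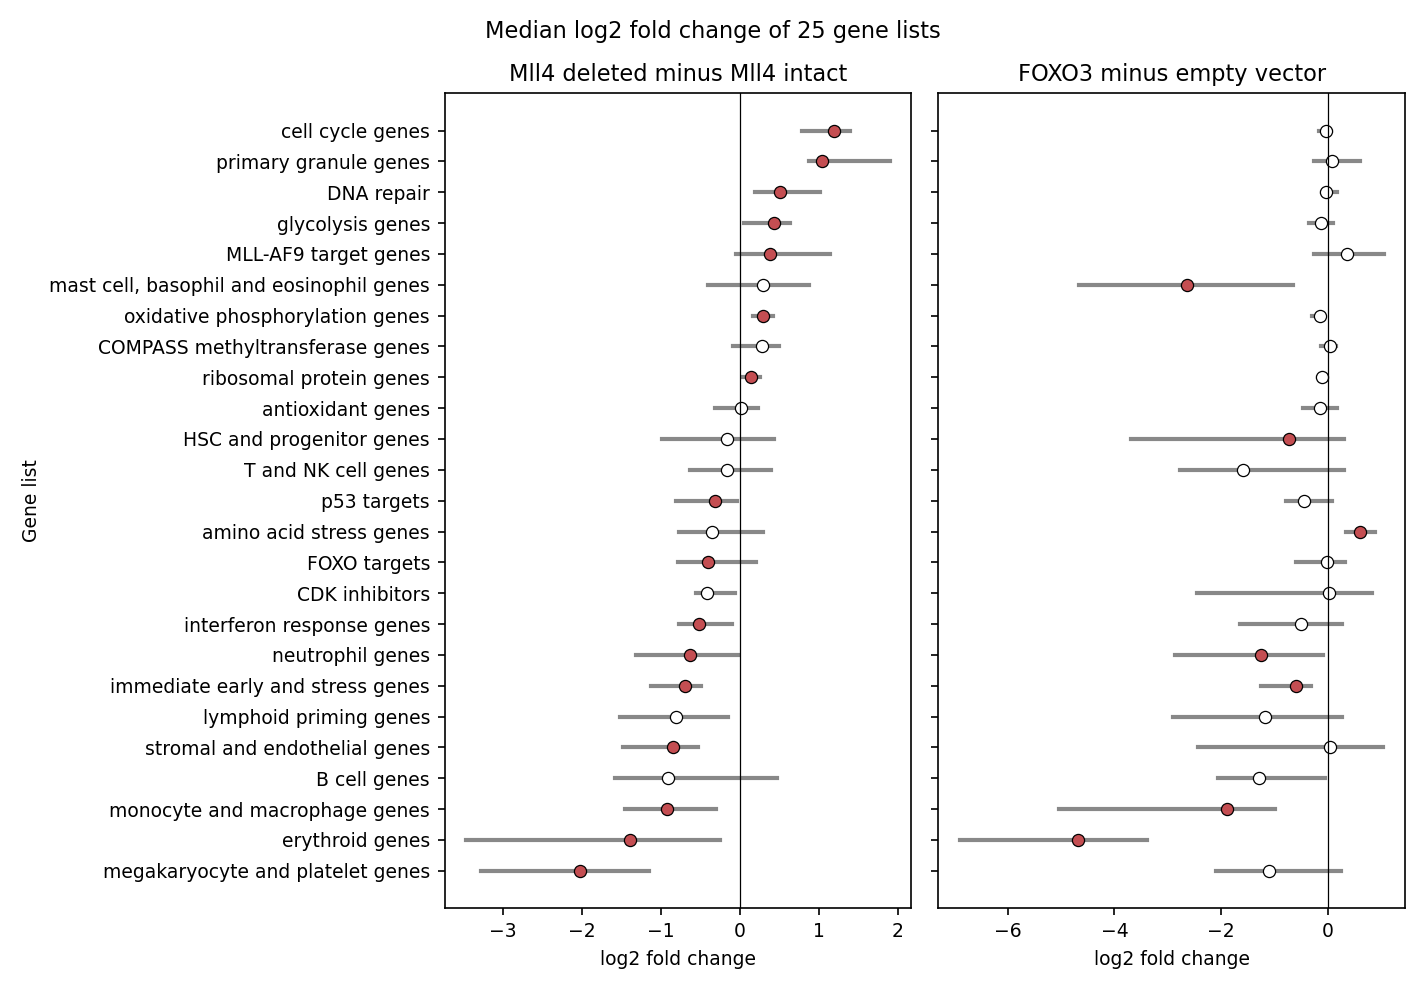
Median log2 fold change (horizontal axis) of the members of 25 gene lists for Mll4 loss (left) and for FOXO3 expression (right), with grey bars from the first to the last quartile of the members. Red points passed an adjusted p of 0.05 by camera with its preset correlation, 16 lists on the left and 7 on the right.

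Whether FOXO3 moved the genes changed with Mll4 loss was read from the overlap of both comparisons, which share no library. Across 14997 genes, which are not independent replicates, their log2 fold changes had a Pearson r of 0.074 and a Spearman rho of −0.003. Genes lower in both numbered 143, where 51.3 were expected of independent lists (Fisher's exact test, two-sided p = 1.18e-30). Those lower with Mll4 loss and higher with FOXO3 numbered 57, where 22.9 were expected (Fisher's exact test, p = 1.54e-10). Il7r (−2.36 for Mll4 loss and −4.88 for FOXO3), Chil3 (−1.62 and −4.26) and Ank1 (−3.82 and −6.88) were lower in both, while Tgm2 (−2.28 and 2.06) was lower in the first and higher in the second. Ank1 was low in most groups, at 0.119 CPM in the libraries labelled Mll4 deleted, 1.34 in the intact ones and 0.112 with FOXO3. Its fall with FOXO3 thus rests on the lone empty-vector library, at 12.97 CPM. For genes higher with Mll4 loss, 60 were lower with FOXO3 and 29 higher, where 58.9 and 26.3 were expected (Fisher's exact test, p = 0.889 and 0.539). With the FOXO3 pair summed, 16 genes were lower in both, where 1.25 were expected. Lower with Mll4 loss and higher with FOXO3 were then 2, where 0.273 were expected. Of those higher with Mll4 loss, 2 were lower with FOXO3 and 0 higher, where 1.79 and 0.393 were expected. Both comparisons take each gene's spread from one fit, so their calls are not independent, and how much this adds to the overlap was not tested. As sets, the genes higher and the genes lower with Mll4 loss did not pass in the FOXO3 comparison (camera adjusted p = 0.212 for each, and adjusted p = 0.669 for each with an estimated correlation). Their medians were −0.09 and −0.08 against −0.04 for all genes.

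**Figure D3:**
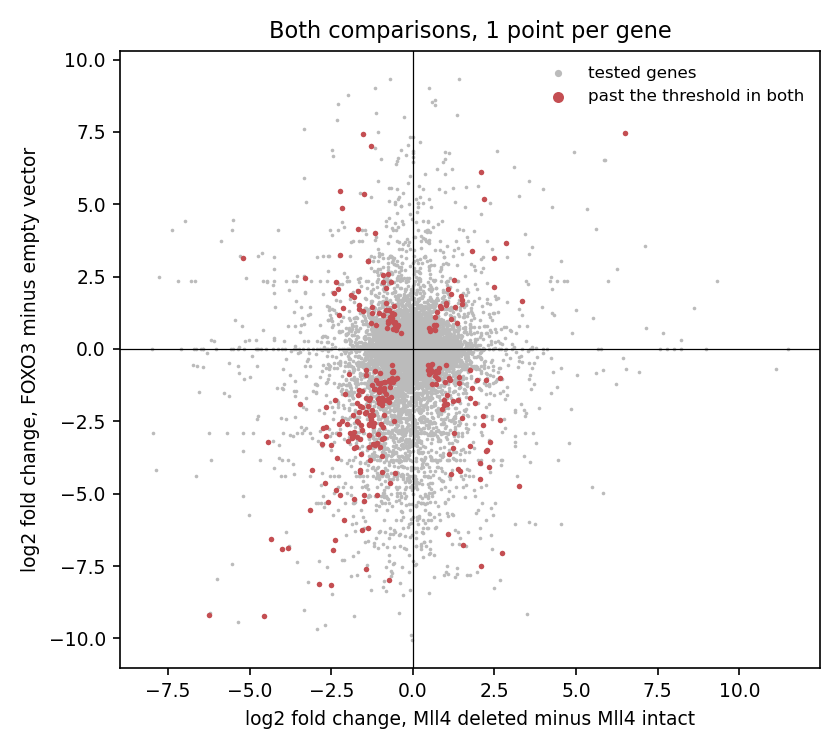
Log2 fold change of each of 14997 tested genes for Mll4 loss (horizontal axis) and for FOXO3 expression (vertical axis), with 1 point per gene. Red points passed the threshold in both comparisons and lie in all 4 quadrants, most often (143) where both are lower.

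LSK cells were compared to see what Mll4 loss does in untransformed stem and progenitor cells, with 1 library of about 50 cells per genotype and therefore no replicate check and no test. Immediate early genes were lower in the library labelled Mll4 deleted. Fos stood at 461 against 1682 CPM in the library labelled wild type (log2 ratio −1.87, 95% exact binomial interval −1.90 to −1.84), Egr1 at 77.6 against 1011 CPM (−3.70, −3.77 to −3.64) and Ier2 at 382 against 1067 CPM (−1.48, −1.51 to −1.45). The median log2 ratio of the 21 such genes, 5 of them positive, was −1.86, below all of 10000 random lists matched on expression (percentile 0). Random lists draw genes independently, whereas genes of 1 list can move together, so the percentile measures no spread between animals and does not test genotype. Mast cell, basophil and eosinophil genes had a median of 1.46 over 11 members (percentile 98.6), 3 of them negative, with the granule membrane gene Cd63 at 148 against 53.2 CPM and, the other way, the transcription factor Gata2 at 146 against 269 CPM (−0.88). Erythroid genes had a median of −1.73 over 9 members (percentile 3.46), with Car2 at 469 against 1562 CPM and the biliverdin reductase Blvrb at 3.21 against 124 CPM. Of 24 lists placed this way, the immediate early and mast cell lists were the 2 outside the central 95% of their random lists and 22 lay inside. Among so many lists, some would lie outside that range without any difference between the genotypes.

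Among lists inside that range, FOXO target, antioxidant, p53 target and DNA repair genes had medians of 0.16, 0.01, 0.10 and 0.02. Cell cycle genes had −0.12, primary granule genes −0.62, neutrophil genes −0.78, macrophage genes −0.21, MLL-AF9 target genes −0.26 and stem cell genes −0.41. COMPASS, interferon, amino acid stress, glycolysis and oxidative phosphorylation genes had medians of 0.23, −0.40, 0.10, −0.53 and 0.36. The T and NK cell, lymphoid priming, megakaryocyte, stromal and ribosomal lists had medians of −0.78, −0.42, −0.33, −0.81 and −0.03. Sex-linked genes had one of 1.98 (percentile 97.1), with Ddx3y at 372 counts in the library labelled Mll4 deleted and 22 in the other. Cell cycle members went both ways, Pcna with a log2 ratio of 1.88 and Mcm3 with −1.84. Mpo stood at 196 against 452 CPM (−1.21), Myc at 627 against 402 CPM (0.64), Meis1 at 127 against 162 CPM (−0.35), Sod2 at 74.15 against 50.1 CPM (0.57) and Cat at 59.4 against 109 CPM (−0.88). Kmt2a had a log2 ratio of −1.73 and Kmt2b one of 2.20. Foxo3 and Csf1r had 0 counts in both libraries, which allows up to 0.116 CPM in the library labelled Mll4 deleted and 0.113 CPM in the other.

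Single genes scattered widely between these LSK libraries. Of 3284 genes with at least 50 CPM in the higher library, 31.6% were more than 4-fold apart, against 1.72% between the MLL-AF9 libraries labelled Mll4 deleted and 0.23% between the intact pair. Ranked with 1 CPM added to both values, the highest log2 ratios were those of Atad3a, Eftud2 and Tbl3 (6.23, 6.07 and 6.07) and the lowest those of Ubr4, Urod and Fkbp5 (−7.22, −7.21 and −7.08). Acss2 and Golm1 had 0 counts in the library labelled Mll4 deleted and were at least 1150-fold and at least 988-fold lower there, against a floor of 3 counts.

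Of 1647 genes past the threshold for Mll4 loss in MLL-AF9 cells with a mean of at least 1 CPM in LSK cells, 49.5% had the same sign in LSK cells. Of the 990 higher, 47.6% were positive in LSK cells and of the 657 lower, 52.4% negative, beside 46.5% and 53.5% of all genes, and genes are not independent. Across 9983 genes the ratios of both cell kinds had a Pearson r of 0.036 and a Spearman rho of 0.024. Mpo was higher in the MLL-AF9 libraries labelled Mll4 deleted (1.90) and lower in the LSK one (−1.21). The LSK and MLL-AF9 libraries were made by different protocols, and the difference between them was not tested.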

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

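All tests of explanations in this part were chosen after the result was seen. Among 106 genes named for Mll4 loss in MLL-AF9 cells, some moved one way in both libraries labelled Mll4 deleted and the opposite way between the LSK libraries, beyond the counting interval. That difference was not tested, and LSK cells have 1 library per genotype, with single genes far apart between those libraries. Opposite signs were common, as 49.5% of the 1647 called genes with a mean of at least 1 CPM in LSK cells had the same sign. The genes given here were picked for opposite signs and do not stand for their lists. Of all cell cycle members at that level, 16 were positive and 20 negative in LSK cells. Primary granule genes had 2 and 6, glycolysis genes 5 and 13, oxidative phosphorylation genes 22 and 16, and ribosomal protein genes 35 and 36. Primary granule genes higher in MLL-AF9 cells had LSK log2 ratios of −0.31 for Prtn3, −0.63 for Ctsg and −1.21 for Mpo. Cell cycle genes stood at −0.52 for Top2a, −1.84 for Mcm3 and −1.39 for Rrm2. Glycolysis, oxidative phosphorylation and ribosomal genes stood at −1.29 for Pfkm, −1.10 for Tpi1, −0.77 for Pgk1, −0.15 for Pkm, −1.31 for Ndufa4, −2.73 for Sdha and −0.17 for Rpl3. Other genes higher in MLL-AF9 cells stood at −4.40 for Sesn1, −1.11 for Ddb1, −0.67 for Dpy30, −1.99 for Paxip1, −1.68 for Ckap2, −1.09 for Myb, −1.75 for Cers4 and −2.40 for Plac8. Genes lower in MLL-AF9 cells had LSK log2 ratios of 1.495 for Il7r, 0.43 for Gadd45a, 4.71 for Ccnd1, 0.69 for Eya1, 0.50 for Ifit1, 0.22 for Irf9, 0.13 for Acta2, 0.60 for Msra and 1.41 for Ncoa6.

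Cell cycle and primary granule genes were higher and macrophage genes lower in the libraries labelled Mll4 deleted. Sex of the mice cancels from the means of groups with 1 library of either sex. A difference between the sexes alone therefore does not give these group differences. Values within each sex follow from the group difference and the spread between libraries, and are no separate test. Cell cycle and primary granule genes had median log2 differences, deleted minus intact, of 0.93 and 1.391 between the female libraries. Between the male libraries they had 1.437 and 1.387, with at most 0.322 and 0.296 between 2 libraries of a group. Macrophage genes were lower in both sexes, with −1.352 and −0.519, but the spread between libraries, up to 0.852, stays open for them. The cell cycle median minus the macrophage median, which no scaling factor changes, differed by 1.743 between the groups and by at most 0.68 between 2 libraries of a group, against scaling moved by a few abundant genes as the whole cause. A smaller share of 1 kind of macrophage-like cell would lower alike those abundant genes that the remaining cells lack. Chosen by a low level in the empty-vector library, 22 macrophage genes had log2 fold changes from −3.148 to 1.525. Their SD was 1.061 beside a median SE of 0.405. These values cannot decide, because the choice rests on the other transformation and the remaining cells may express such genes. This explanation stays open as well. Open are the loss of Mll4, the Cre retrovirus that goes with it, a difference between cultures and a shift in the stages of maturation, and none of these was tested.

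Erythroid and mast cell, basophil and eosinophil genes were lower in the FOXO3 libraries. Erythroid genes stood at a mean log2(CPM + 1) of 3.439 in the lone empty-vector library and at 1.158 and 1.128 with FOXO3, against 1.335 to 1.901 in the 4 libraries of the other transformation, and mast cell, basophil and eosinophil genes at 5.461, 3.271 and 3.247 against 5.037 to 6.779. Cells of other lineages in the empty-vector library stay open for both, because 17 of 23 other lists also had an empty-vector level outside those 4 libraries, so levels of the other transformation decide nothing here. A difference between single cultures stays open as well, since the FOXO3 libraries differed by only 2.015 in chi-square per degree of freedom and the empty vector has 1 library, and so does an effect of FOXO3.

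Kmt2d was not lower in the libraries labelled Mll4 deleted. A deletion that takes away at least 50% of the counted transcript is argued against by the log2 fold change of −0.01 ± 0.16. A loss of some exons from a transcript that is still counted stays open, as counts per exon were not used here. Exchanged labels of the LSK libraries, with a Kmt2d log2 ratio of 2.883, stay open too, because 31.6% of well expressed genes were more than 4-fold apart between those libraries.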

How the results depend on the processing

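The alternatives that sum the FOXO3 pair or add the sex of the library were chosen after the result was seen. For Mll4 loss the 2237 genes became 3540 with total counts, 3695 with DESeq2 and 1010 at a 2-fold threshold. With the FOXO3 pair summed 312 passed, 302 and 314 without FOXO3 library 1 or 2, and leaving out another library gave 787 (without intact library 1) to 3106 (without the library labelled Mll4 deleted 2). With only the 4 libraries compared edgeR called 0 (3498 at an unadjusted p under 0.05), and 0 with sex as a covariate in those 4 (2453 at an unadjusted p under 0.05), where DESeq2 was not run. Adding sex as a covariate to the fit of 7 libraries gave 1910 calls and kept 1649 of the 2237. With the replicate number as a block in those 4, 893 passed in place of 0; deviations of same-numbered libraries correlated with r = 0.327 across genes, but only 2 pairs exist and they cross the sexes, so the number was not taken to pair them. For FOXO3 the 1069 genes became 9710 with only the 3 libraries compared, whose spread rests on the FOXO3 pair, 2178 with DESeq2 and 178 with the pair summed, and 159 and 140 without FOXO3 library 1 or 2. No called gene changed sign under these alternatives. Camera kept all 16 and 7 list calls with the pair summed. With an estimated correlation 0 of the 16 list calls for Mll4 loss and 0 of the 7 for FOXO3 held by camera. The correlation of both comparisons, 0.074, was 0.116 over genes with a mean of at least 5 CPM and 0.012 (without intact library 1) to 0.164 (without the library labelled Mll4 deleted 1) with a library left out. For Mll4 loss the mast cell, basophil and eosinophil median was −0.819 and Meis1 −1.108 without the library labelled Mll4 deleted 1, and 0.83 and 0.922 without the library labelled Mll4 deleted 2. Except where an alternative uses fewer libraries or a fold threshold by construction, the cause was not tested. Over single genes and all alternatives, 2791 values kept their side of the threshold, 506 lost the call and 142 gained one. Another 1 changed sign with a call in 1 of the fits. Over lists the numbers were 221, 28, 10 and 1 in the same order. In LSK cells 150 values, of single genes and of lists, stayed in place and 25 moved. Ratios of single genes were judged against their counting interval. Percentiles of lists have no such interval and were judged by whether they crossed an edge of the central range of their random lists. The LSK libraries give a limit of 0.116 and 0.113 CPM for a count of 0.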

Other observations

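The comparison of levels in this part was chosen after the values were seen, and the difference between transformations was not tested. The MLL-AF9 cells of the separate transformations differed in level. Hoxa9 stood at 148 ± 1.49 CPM in the FOXO3 and 94.9 CPM in the empty-vector library, and at 10.3 ± 1.02 and 2.84 ± 0.0717 CPM in the libraries labelled Mll4 deleted and intact. Cdkn1a stood at 50.7 ± 1.11 and 85.3 CPM against 526 ± 26.9 and 666 ± 41.0 CPM, and Csf1r at 1.81 ± 0.154 and 7.46 CPM against 279.7 ± 175 and 305 ± 66.4 CPM, in the same order. The mean log2(CPM + 1) of the macrophage list was 2.91 and 2.90 with FOXO3 and 4.35 with the empty vector, against 7.10 and 7.68 in the pair labelled Mll4 deleted and 7.84 and 7.98 in the intact pair. Cell cycle genes stood at 7.47 and 7.48 with FOXO3 and 7.43 with the empty vector, against 6.597, 6.89, 5.39 and 5.37 in the same pairs. The transformation and the retrovirus used are confounded with these groups.

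An unmatched gene number was the most abundant of the empty-vector library, with 0.961% of its counts.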
